A study of Homo sapiens with 15 samples.

How the data were processed

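Bisulfite sequencing of messenger RNA was analysed in 15 libraries from the human pancreatic cancer lines BxPC-3, MiaPaCa-2 and PANC1. Bisulfite turns unmethylated cytosine into uracil, so a cytosine that is still read as cytosine counts as 5-methylcytosine (m5C) or as unconverted. Each line had 3 control libraries and 2 knockdown libraries. In each line 1 control was untreated and 2 carried a control lentivirus, and both knockdown libraries carried a lentivirus with a short hairpin against NSUN2. The labels give polybrene at 2 µg/ml and puromycin at 1 µg/ml for BxPC-3 and MiaPaCa-2. For PANC1 they give 4 µg/ml of each, so these doses differ with the line. The labels do not say whether the 2 knockdown libraries of a line used the same hairpin. They also do not say that replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical. Per the labels, 4 libraries (MiaPaCa-2 knockdown 2, PANC1 control 3 and both PANC1 knockdowns) have a transcriptomic library source and the other 11 a genomic one. This split was treated as a possible batch.

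Per the labels' protocols, poly(A) RNA was enriched with oligo(dT) beads, converted with bisulfite and made into strand-specific libraries without a fragmentation step. The submitters' processing notes name bcl2fastq, Trim Galore and the GRCh38 (hg38) genome, with no versions. The aligner, the site caller and the filters on reads are not given in the sources used here. Per the file header, the deposited table lists NSUN2-dependent m5C sites, with a coverage and a methylation level for each library and site. Coverage in the deposited table is a whole-number count of reads per cytosine and library. The level is a fraction between 0 and 1 that the authors gave for each cytosine and library. All positions are hg38, as deposited.

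The values show how the authors filtered the table. A level was given wherever the deposited coverage was at least 10 and was absent below that. No level lay between 0 and 0.05, so every level under 0.05 was written as 0, and a written 0 is not proof of an unmethylated site. Each site was listed in 2 or 3 lines. In every line the lowest mean control level and the lowest fall on knockdown were both 0.05. The sites were therefore chosen on the difference that is tested. Falls in mean level and counts of sites that fell, with their p-values, are not independent evidence of that difference.

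The test planned for counts was replaced by limma 3.58.1 on the level, because exact methylated reads cannot be recovered. Alternatives that need such reads took level times coverage, rounded, as an approximation. Levels under 0.05 are lost, and the levels are not exact fractions of the deposited coverage. The text cells that mark missing levels also kept the 2 kinds of library column from being recorded as plain counts and fractions, so their ranges were checked separately. Sites were tested over all lines when at least 2 control and 2 knockdown libraries of each line had a level, with cell line as a covariate. The same limma model with a knockdown term per line gave the tests within a line and the test of the difference between lines. In these tests the lines shared the estimate of the spread at a site. Control levels were compared between lines with limma's moderated F-test. P-values were adjusted by the Benjamini-Hochberg method over the tested sites, with a threshold of 0.05. Mean levels per library were compared by exact two-sided permutation of the labels within each line, which gives 1000 arrangements over 3 lines and 10 within a line. The test of untreated against control-virus libraries has 27 arrangements. Levels were simulated at 638 sites with the real control means. Their spread per site was averaged over the controls of the 3 lines and used in both arms. In these levels, limma over all lines recovered 0.5% of 200 sites with a 25% fall, 28.0% with a 50% fall and 64.0% with a 90% fall. Of the calls at the 90% fall, 5.19% were unchanged sites. Within BxPC-3, 13.5% of the sites with a 90% fall were recovered. The spread and number of tested sites of BxPC-3 itself differ, so this share is not its real power. In the real data all 638 sites were lower after knockdown, not only 200, so the all-line shares are not the real power either. No pair of libraries held the same levels.

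Sites were named by a rule. It took the 10 largest falls over all lines, the 5 largest falls within each line, the 5 smallest p-values of the difference between lines and among controls, up to 3 sites with the highest coverage in each gene list, and all sites in genes of the RNA cytosine methylation machinery. The rule gave 63 sites. It also asked for rises and for sequence context classes: no site rose in the limma tests, and context classes were not analysed because no genome sequence was used. There were 14 gene lists: ribosomal proteins, translation factors, oxidative phosphorylation, proteasome, glycolysis, cytoskeleton, adhesion and matrix, RNA binding and splicing, chaperones and secretory pathway, cell cycle, pancreatic cancer genes, RNA cytosine methylation machinery, mRNAs named as NSUN2 targets elsewhere, and non-coding NSUN2 targets. A list was set against all other tested sites by Fisher's exact test. The design, the alternatives, the lists and the naming rule were fixed before the data were examined, whereas the use of coverage as a measure of transcript abundance, the mitochondrial sites and the exchange of 2 coverage columns, described next, were taken up after seeing the data.

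In MiaPaCa-2 the levels of control 1 and knockdown 2 were fractions of each other's deposited coverage column more often than of their own. Levels were used as deposited. Coverage is as deposited unless the text says that the columns were exchanged. Reads at the NSUN2 site were scaled to the reads at listed nuclear sites of the library. Coverage of genes, with exchanged columns unless stated, was summed over listed nuclear sites with a coverage value in all libraries, for genes with a mean of at least 20 reads, scaled to the library's total and tested with limma on log2(value + 1). In simulated coverage of 559 genes, this recovered 86.0% of 50 genes with a log2 fall of 1 and 100% with a log2 fall of 2, and 6.52% and 9.09% of the calls were unchanged genes. The reads at listed sites are not the depth of the library, which is unknown here. Symbols were taken from the table; of 2539 sites with a single symbol, 2391 matched the reference gene table. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6, matplotlib 3.10.9 and R 4.3.3 were used. Alternatives covered the coverage minimum (20 and 30), the scale of the level, other tests, control-virus libraries only, library source, a replicate block and leaving out each library.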

Results

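Messenger RNA m5C was measured at single cytosines in 3 pancreatic cancer lines, BxPC-3, MiaPaCa-2 and PANC1, to ask which sites depend on NSUN2, a methyltransferase that places m5C on tRNA and mRNA. Each line gave 3 control and 2 NSUN2 knockdown libraries. The table held 2829 cytosines in 1983 genes, of which 672 were listed in all 3 lines and 2157 in 2 lines. BxPC-3 had 1295 listed sites, MiaPaCa-2 2383 and PANC1 2652. The median control level of a listed site was 0.111 in BxPC-3, 0.123 in MiaPaCa-2 and 0.139 in PANC1, and control levels of at least 0.5 were found at 42, 100 and 160 sites. CTBP1, a transcriptional corepressor, had 9 listed sites, while 1551 genes had 1. The mitochondrial genome carried 197 sites, 76 of them in MT-ND5. Of the 197, 156 had another listed site within 10 nt, against 84 of 2632 nuclear sites. Reads at listed sites ranged from 273397 to 1140169 per library, and the median coverage of a site from 36 to 124. All sites had been selected for a lower level after knockdown, so a fall at a listed site was fixed by the selection.

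NSUN2 itself carried a listed cytosine (chromosome 5, position 6599910, minus strand), and the reads that cover it were used to compare its transcript between libraries. Per 1000000 reads at listed nuclear sites, BxPC-3 controls had 2383 ± 175 reads (SD, n = 3) and knockdowns 301 ± 40.1 (n = 2), or 12.6% of control. PANC1 controls had 530 ± 182 and knockdowns 177 ± 12.7, or 33.3%. In MiaPaCa-2 the deposited coverage gave 686 ± 441 in controls and 430 ± 253 in knockdowns, because the library labelled control 1 had 184 scaled reads, below the 251 of knockdown 1, and the library labelled knockdown 2 had 609. The levels of these 2 libraries were those of their labels: the NSUN2 site was at 0.577 in control 1 and at 0.099 in knockdown 2. With the 2 coverage columns exchanged, MiaPaCa-2 controls had 828 ± 202 scaled reads and knockdowns 218 ± 47.6, or 26.3%. Over all lines reads at the site fell by 1.66 on the log2 scale as deposited (exact two-sided permutation test, p = 0.008) and by 2.14 with the exchange (p = 0.001, the smallest the test can give). The NSUN2 site also lost methylation, from 0.536 ± 0.0957 to 0.0445 ± 0.0629 in BxPC-3, from 0.571 ± 0.0797 to 0.099 ± 0 in MiaPaCa-2 and from 0.218 ± 0.0316 to 0.0395 ± 0.0559 in PANC1.

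**Figure D1:**
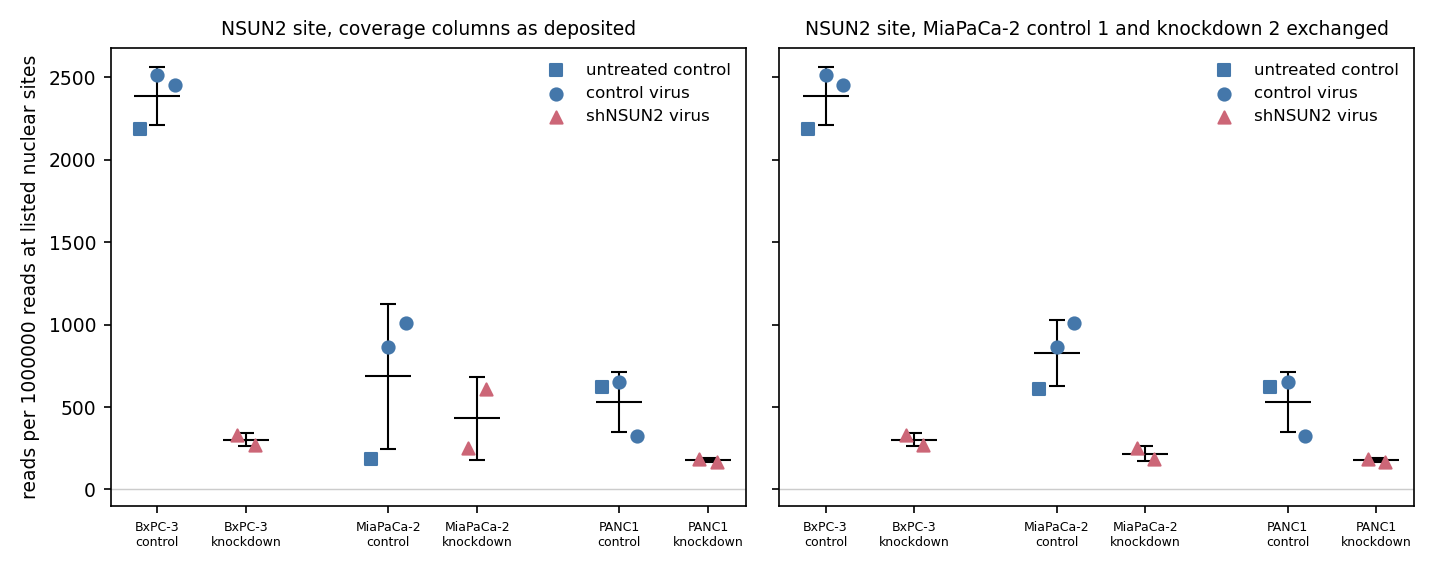
Reads at the NSUN2 site per 1000000 reads at listed nuclear sites, for each library of the 3 lines, with coverage as deposited (left) and with the coverage columns of MiaPaCa-2 control 1 and knockdown 2 exchanged (right). Points are libraries, black bars the mean and SD of a group; BxPC-3 knockdowns average 301 against 2383 in controls.

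The average listed site lost most of its methylation in each line. Over the 602 sites with a level in all 15 libraries, 5 of them mitochondrial, the mean level was 0.159 ± 0.00797 in BxPC-3 controls (SD, n = 3) and 0.00473 ± 0.00467 in knockdowns (n = 2). It was 0.281 ± 0.0263 and 0.0239 ± 0.0201 in MiaPaCa-2, and 0.283 ± 0.0911 and 0.0252 ± 0.0324 in PANC1. The mean over lines fell by 0.223 (exact two-sided permutation test within lines, p = 0.001, the smallest of its 1000 arrangements). Since the sites were listed for a fall, this p-value is not independent evidence of one. Within a line, over the sites with a level in its 5 libraries, the mean fell by 0.144 in BxPC-3 (1151 sites), by 0.159 in MiaPaCa-2 (2153 sites) and by 0.168 in PANC1 (2433 sites), each with p = 0.1, which is the smallest that 3 against 2 libraries allow in an exact permutation test. Among libraries with a genomic source the mean fell by 0.154 in BxPC-3 and by 0.243 in MiaPaCa-2 (3 controls, 1 knockdown), and among those with a transcriptomic source it fell by 0.356 in PANC1 (1 control, 2 knockdowns); PANC1 had no knockdown library with a genomic source. In each line knockdown 1 lay above knockdown 2, with means of 0.00803 and 0.00143 in BxPC-3, 0.0381 and 0.00967 in MiaPaCa-2, and 0.0482 and 0.00228 in PANC1. Both MiaPaCa-2 control 1 and knockdown 2 held written levels of 0 at sites with few reads in the other's coverage column, 159 of 161 such levels in control 1.

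**Figure D2:**
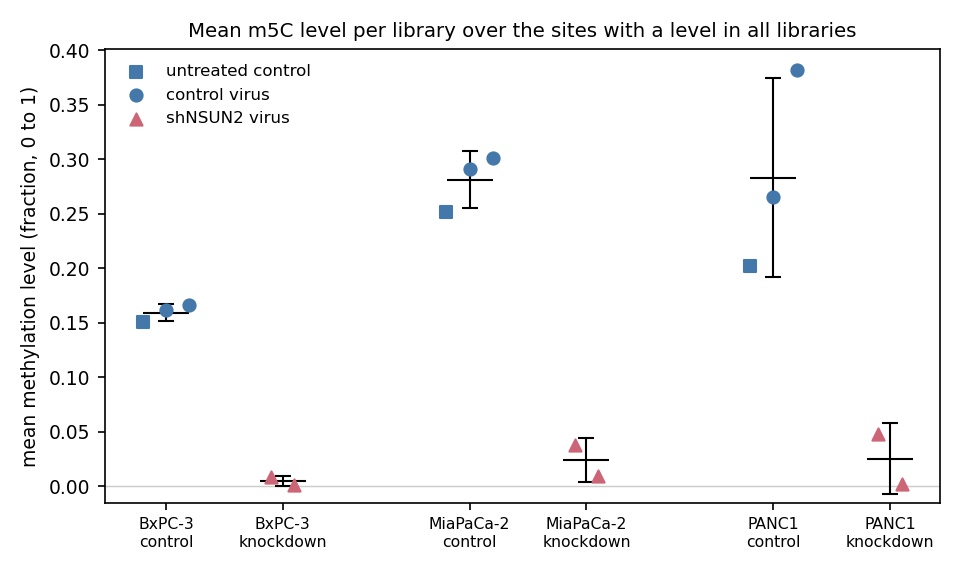
Mean methylation level (fraction) of each library over the 602 sites with a level in all libraries, by line and arm. Squares are untreated controls, circles control-virus and triangles knockdown libraries, with black bars for the group mean and SD; the knockdown libraries of BxPC-3 lie at 0.00803 and 0.00143 and its controls between 0.15 and 0.166.

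Highly methylated sites of single genes lost most of their m5C in all 3 lines, on the mean of the 2 knockdown libraries. The largest fall over all lines was in TMEM238, which encodes a little-studied membrane protein (chromosome 19, position 55383848, minus strand), from 0.903 ± 0.018 to 0.114 ± 0.161 in BxPC-3, from 0.879 ± 0.0258 to 0.229 ± 0.208 in MiaPaCa-2 and from 0.855 ± 0.00346 to 0.129 ± 0.182 in PANC1, at coverages of 90 to 324. Next came NIBAN2, a cytoplasmic phosphoprotein (chromosome 9, 127506470, minus), SLC35B4, a Golgi nucleotide sugar transporter (chromosome 7, 134293043, minus), KREMEN2, a receptor that restrains Wnt signalling (chromosome 16, 2967119, plus), and SZRD1 (chromosome 1, 16396655, plus). Their levels fell by 0.712 ± 0.0572 (SE), 0.703 ± 0.0522, 0.682 ± 0.0698 and 0.66 ± 0.0429 (limma, adjusted p = 1.21e-07, 5.74e-08, 1.83e-06 and 2.59e-08). TMEM238 itself fell by 0.722 ± 0.0497 (adjusted p = 3.55e-08). The SLC35B4 site had only 12 to 56 reads per library, and KREMEN2 lacked a level in 1 BxPC-3 control. In PANC1 knockdown 1 KREMEN2 was still at 0.519 and NIBAN2 at 0.432, while both were at 0 in PANC1 knockdown 2. The other sites among the 10 largest falls lay in ARPIN (overlapped by ARPIN-AP3S2), an inhibitor of actin branching, ZDHHC8, a palmitoyltransferase, PIK3R4, the regulatory subunit of an autophagy lipid kinase, SDF4, a calcium-binding protein of the Golgi lumen, and CDK5RAP3, a factor of the UFM1 pathway, which fell by 0.635, 0.627, 0.625, 0.583 and 0.582. SDF4 had only 5 to 24 reads per library and a level in only 2 controls of BxPC-3 and 2 of MiaPaCa-2. Of 638 sites that could be tested over the 3 lines, 631 fell and 0 rose (limma, 631 with an unadjusted p below 0.05). All 638 had a lower mean after knockdown, as their selection required. At a minimum of 30 reads, with coverage as deposited, the test covered 379 sites, of which 378 fell.

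Each list of genes fell as far as it could be tested, while whether a list stood apart from the other sites could not be told. All sites had been listed for a fall, so the counts and p-values per list are not independent evidence of one. All 10 tested sites in ribosomal protein mRNAs fell, with a mean difference of −0.201, among them RPS3 (chromosome 11, 75404677, plus; −0.286 ± 0.0385, adjusted p = 1.23e-05 by limma) and RPS19 (chromosome 19, 41869138, plus; −0.104 ± 0.0229, adjusted p = 0.000673), at coverages of 5077 to 7695 for RPS19. Translation factors fell at 3 of 3 sites, including EIF2S3, a subunit of the factor that brings the initiator tRNA (−0.321). Among oxidative phosphorylation mRNAs, 2 of 2 sites fell, both in NDUFB7, a subunit of the respiratory NADH dehydrogenase, one from high levels (0.493 to 0.0265 in BxPC-3, 0.726 to 0.114 in MiaPaCa-2 and 0.561 to 0.0375 in PANC1) and one from low levels (−0.135). Proteasome sites fell at 2 of 2 (PSMD2 −0.174 and PSMD3 −0.177), cytoskeleton sites at 4 of 4, and adhesion and matrix sites at 9 of 9, with the integrin subunits ITGA3 at −0.187 and ITGB1 at −0.174. Chaperone and secretory pathway sites fell at 2 of 2, SEC31A of the vesicle coat (−0.0878) and a site where SSR1 and CAGE1 overlap (−0.304). Cell cycle sites fell at 3 of 3, and the largest of these was again CDK5RAP3. Among pancreatic cancer genes GNAS, a G protein subunit (−0.255 ± 0.0288), and the mucin gene MUC1, overlapped by AL713999.1 (−0.527 ± 0.0543), fell, 2 of 2 tested. In the machinery list the tested site was that of NSUN2 (−0.381 ± 0.0493, adjusted p = 8.68e-06), and in the list of non-coding targets it was that of RPPH1, the RNA of RNase P (−0.419 ± 0.0578). Among mRNAs named as NSUN2 targets elsewhere, 5 of 5 sites fell, including HDGF, a growth factor gene (chromosome 1, 156743366, minus), by 0.471 ± 0.0495 (adjusted p = 1.58e-06) and QSOX1, a secreted sulfhydryl oxidase, at 2 sites (−0.181 and −0.129). Glycolysis and RNA binding lists had 0 sites testable over all lines. The count of sites that fell was the same adjusted over the list alone in each of these lists, and Fisher's exact test against the other sites gave p = 1 throughout, which 631 falls among 638 sites leave little room to change.

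In BxPC-3 the largest falls were those of SLC35B4 (from 0.82 to 0.028), TMEM238, NIBAN2, KREMEN2 and SZRD1. In MiaPaCa-2 PIK3R4 fell from 0.761 ± 0.194 to 0, with 11 to 52 reads, followed by DENND5B, an exchange factor for Rab proteins (0.907 to 0.153), ULK2, an autophagy kinase (0.792 to 0.0535), MRPS25 of the mitochondrial ribosome (0.793 to 0.0625) and ABHD17A, a depalmitoylase (0.837 to 0.107). In PANC1 the order was ARPIN (0.793 to 0.025), TMEM238, OGFOD3 (0.815 to 0.091), the orphan receptor GPR153 (0.774 to 0.0575) and COPE, a coatomer subunit (0.798 to 0.089). ARPIN and GPR153 had a level in only 2 PANC1 controls, and COPE had 10 to 45 reads in these controls. In BxPC-3 144 of 1222 tested sites fell, in MiaPaCa-2 791 of 2187 and in PANC1 862 of 2574, and 0 rose in any line (limma; 340, 1069 and 1257 sites had an unadjusted p below 0.05). Ribosomal protein sites fell at 3 of 14 in BxPC-3, 15 of 35 in MiaPaCa-2 and 11 of 36 in PANC1. Adhesion and matrix sites fell at 3 of 19, 16 of 31 and 21 of 35. Glycolysis sites fell at 2 of 3 in MiaPaCa-2, with PFKM (−0.161, adjusted p = 0.0456) and ALDOA, overlapped by AC093512.2 (−0.124, adjusted p = 0.0465), and at 1 of 3 in PANC1. RNA binding sites fell at 0 of 4 in BxPC-3, 3 of 11 in MiaPaCa-2 and 2 of 7 in PANC1. BxPC-3 also had no fall past the test in the proteasome (0 of 2) or chaperone and secretory pathway (0 of 6) lists. These had 3 of 8 and 6 of 14 in MiaPaCa-2 and 2 of 7 and 5 of 11 in PANC1. The spread at a site was shared over the lines, so a missing call in BxPC-3 does not show a missing loss there. PSMD3 went from 0.0807 ± 0.0142 to 0 in BxPC-3 (limma, adjusted p = 0.342), while its SD in PANC1 controls was 0.157. A site in HNRNPH1, a splicing factor, had levels of 0.22 ± 0.0393 and 0.148 ± 0.00919 in MiaPaCa-2 and of 0.288 ± 0.199 and 0.171 ± 0.126 in PANC1 (adjusted p = 0.51 and 0.311), and one in SRSF2 had 0.283 ± 0.104 and 0.167 ± 0.0127 in BxPC-3 and 0.323 ± 0.083 and 0.207 ± 0.0757 in MiaPaCa-2 (adjusted p = 0.267 and 0.198), so these sites were not shown to change. The NSUN5 site, in a gene for an rRNA methyltransferase, went from 0.086 to 0 in MiaPaCa-2 and from 0.108 to 0 in PANC1 without passing the test. These counts rest on few libraries: without knockdown 1 of the line they were 35, 320 and 279, without knockdown 2 they were 25, 220 and 117, without BxPC-3 control 2 or 3 they were 85 and 93 in BxPC-3, without PANC1 control 3 they were 295 in BxPC-3 and 1208 in MiaPaCa-2, and without PANC1 control 1 they were 1444 in PANC1. They were 221 in BxPC-3 and 1573 in PANC1 with control-virus libraries only. Under a quasi-binomial model they were 400 in BxPC-3, 879 in MiaPaCa-2 and 0 in PANC1. Counts in the same order of lines were 627, 1418 and 1431 on the logit scale. By Fisher's exact test on pooled reads, which leaves out the spread between libraries, 974, 1803 and 2332 sites changed.

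The size of the loss was not shown to differ between lines at any site. The smallest p-value belonged to RPPH1 (chromosome 14, 20343234, minus; unadjusted p = 0.000209, adjusted p = 0.133 by limma), which fell by 0.682 in BxPC-3, by 0.338 in MiaPaCa-2 and by 0.236 in PANC1. The next were TSEN34, a subunit of the tRNA splicing endonuclease (adjusted p = 0.248), ACOT8, a peroxisomal thioesterase, TCOF1, a nucleolar factor, and GCN1, a regulator of translation under stress (adjusted p = 0.297 each). In these 4 the differences were smaller in BxPC-3 (−0.065, −0.182, −0.135 and −0.134) than in MiaPaCa-2 (−0.329, −0.431, −0.434 and −0.433), as were the control levels they started from. Of 638 sites 0 passed the limma test of the difference and 63 had an unadjusted p below 0.05. Without PANC1 control 1, 6 sites passed, among them RPPH1, ACOT8, GCN1 and TCOF1, while RPPH1 alone passed without PANC1 control 3 and a site in AGO1, a gene of small RNA silencing named after its value was seen, without BxPC-3 control 3.

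BxPC-3 controls had the lowest m5C on average. Their library means over 621 sites (0.152 to 0.166) lay below those of all other controls (0.202 to 0.384). Single sites also passed a test between lines. How many did depended on single libraries, and some other groupings of the controls gave more sites than the real lines. The labels give PANC1 higher doses of polybrene and puromycin, which cannot be told apart from the line. MRPS25 (chromosome 3, 15051825, minus) stood at 0.287 ± 0.0225 in BxPC-3 (n = 3) against 0.793 ± 0.0461 in MiaPaCa-2 and 0.805 ± 0.128 in PANC1 (adjusted p = 0.00768 by limma). The MUC1 site (chromosome 1, 155186035, minus) was at 0.406 ± 0.0552, 0.679 ± 0.0603 and 0.809 ± 0.0604, and RTN3, a protein of the endoplasmic reticulum (chromosome 11, 63758891, plus), at 0.419 ± 0.0413, 0.746 ± 0.0388 and 0.696 ± 0.038 (adjusted p = 0.0118 each). RPPH1 went the other way, at 0.731 ± 0.0329 in BxPC-3, 0.338 ± 0.0477 in MiaPaCa-2 and 0.273 ± 0.0944 in PANC1 (adjusted p = 0.00768). So did HFM1, a helicase of meiosis (chromosome 1, 91387307, minus), at 0.887 ± 0.0115, 0.109 ± 0.109 and 0.356 ± 0.267 (adjusted p = 0.0118), the last from 2 libraries with few reads. Its coverage in BxPC-3 was 333 to 882 in controls and 3 to 7 in knockdowns, so no level was given there. Of 672 sites 39 passed the limma test between lines (221 with an unadjusted p below 0.05). BxPC-3 was lowest at 33 of them and MiaPaCa-2 highest at 30. Across sites the control levels of any pair of lines correlated with a Spearman coefficient between 0.622 and 0.713, where sites are not independent replicates. The count depended on single libraries: 3, 0 and 1 sites passed without BxPC-3 control 1, 2 and 3, 8 and 2 without MiaPaCa-2 control 2 and 3, 194, 2 and 163 without PANC1 control 1, 2 and 3, and 0 with control-virus libraries only. MRPS25 and RPPH1 were both among the sites that passed without BxPC-3 control 1, without either of these MiaPaCa-2 controls and without PANC1 control 2.

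Untreated cells were not shown to differ from cells with the control virus in mean level. Over the 621 sites with a level in all 9 controls, untreated minus control virus was −0.0117 in BxPC-3, −0.0527 in MiaPaCa-2 and −0.124 in PANC1. The mean over lines was −0.0628 (exact two-sided permutation test, p = 0.0741, where the smallest possible is 0.037). With a library left out it ran from −0.0324 without PANC1 control 1 to −0.0881 without BxPC-3 control 1. Either omission leaves that line without an untreated library. The library means were 0.152 against 0.162 and 0.166 in BxPC-3, 0.244 against 0.292 and 0.301 in MiaPaCa-2, and 0.202 against 0.268 and 0.384 in PANC1. Over all sites with a level in the library the order in BxPC-3 was the opposite, with 0.169 in the untreated library against 0.157 and 0.145, and untreated libraries also had the highest mitochondrial means in BxPC-3 (0.303 against 0.198 and 0.101) and PANC1 (0.383 against 0.235 and 0.168). The exact permutation test reached p = 0.037 on the logit scale, and part of the PANC1 value came from control 3, which has another library source; without the transcriptomic libraries the mean was −0.0435 (p = 0.0556, the smallest of that test).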

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

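The settings with exchanged coverage columns, without mitochondrial sites, with a variance trend, and those that leave out libraries in the comparison of controls or in the test between lines were chosen after seeing the data. The mean level over all lines fell in each of 14 other settings and 15 leave-one-out runs, with differences between −0.157 and −0.243 on the fraction scale. All sites were listed for a fall, so an unchanged direction, here or at named sites, is no independent support for one. No result as a whole turned its direction in these settings, although parts did (untreated BxPC-3 cells over all sites, 3 MT-ND5 sites by Fisher's exact test, and the order of NSUN2 reads in MiaPaCa-2 knockdowns), nor did any of the 5370 alternatives of the 207 tests at named sites, of which 228 lost and 96 gained a call. Deviations of same-numbered libraries had correlations from −0.267 to 0.109. With 2 knockdowns per line the deviations of 1 mirror those of the other, so this cannot decide whether the numbers pair samples. With a replicate block over replicates 1 and 2 the mean fell by 0.202 (exact two-sided test over pairs, p = 0.0312, the smallest possible) and 608 of 621 sites fell. Within BxPC-3, MiaPaCa-2 and PANC1 the block gave 215, 911 and 627 sites. Without a block the same libraries gave 296, 1098 and 849. The 631 sites over all lines became 378 at a coverage minimum of 30 as deposited and 412 with exchanged columns, through fewer sites tested, and 604 to 643 with a library left out. On the logit scale counts within lines were 627, 1418 and 1431; by Fisher's exact test on pooled reads, rebuilt only roughly as level times coverage and without the spread between libraries, 974, 1803 (1875 with exchanged columns) and 2332, of which 1 rose in MiaPaCa-2 and 2 in PANC1, all 3 as deposited and in MT-ND5 (positions 13838, 12562 and 12548, named after their values were seen) with a mean level that fell; under a quasi-binomial model on such reads 400 in BxPC-3 and 0 in PANC1, where the cause was not tested. With control-virus libraries only they were 221 in BxPC-3 and 1573 in PANC1; at sites with a level in every library 449 in MiaPaCa-2 and 508 in PANC1, from fewer sites; without transcriptomic libraries 331 in MiaPaCa-2, while PANC1 could not be fitted. Leaving out a library gave 25 to 295 in BxPC-3 (without its control 2 85, control 3 93, knockdown 1 35, knockdown 2 25, PANC1 control 3 295), 220 to 1208 in MiaPaCa-2 (without its knockdown 1 320, knockdown 2 220, PANC1 control 3 1208) and 117 to 1444 in PANC1 (without its control 1 1444, knockdown 1 279, knockdown 2 117); the lone knockdown library left is assumed to vary like the other groups. The test of the difference between lines called 0 to 6 sites (6 without PANC1 control 1, 1 without BxPC-3 control 3 or PANC1 control 3). The comparison of lines among controls called 0 with control-virus libraries only and 0 to 194 with a library left out: 3, 0 and 1 without BxPC-3 control 1, 2 and 3, 8 and 2 without MiaPaCa-2 control 2 and 3, and 194, 2 and 163 without PANC1 control 1, 2 and 3. Untreated minus control virus passed its exact permutation test on the logit scale (−0.425, p = 0.037) and at a coverage minimum of 20 with exchanged columns (−0.0584, p = 0.037), the smallest p possible, but not at 10 (p = 0.111), and ran from −0.0324 to −0.0881 with a library left out; the cause was not tested. Not run were a coverage minimum of 5 or none, since levels under 10 reads were absent, edgeR, since exact methylated reads cannot be recovered, and sequence context classes and transcript regions, since no genome or exon annotation was used. At 10 reads a level of 0.05 is less than 1 read, so the depth limits low levels most.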

Other observations

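Use of mitochondrial sites, gene coverage, the difference between knockdown libraries and the exchanged coverage columns were all taken up after seeing the data. Among their tests, those on fractions of the other coverage column, on written zeros, on a whole exchange of libraries, on neighbouring sites, on small denominators, on NSUN2 dependence of mitochondrial sites, on reads left at the NSUN2 site, on knockdown levels of at least 0.2, on knockdown levels at sites with high control levels and on other splits of the all-line fit were chosen only after the result was seen.

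Mitochondrial transcripts carried many listed cytosines in dense stretches. MT-ND5 had 76 sites, MT-ND4 16 and MT-ND3 6, all on the plus strand, and a further 94 of the 197 had no gene assigned, 78 of those on the minus strand. Mean mitochondrial levels in BxPC-3 were 0.303, 0.198 and 0.101 in controls and 0.0195 and 0.0164 in knockdowns (190 sites), in PANC1 0.383, 0.235 and 0.168 against 0.0582 and 0.139 (179 sites), and in MiaPaCa-2, where 29 sites were listed, 0.344, 0.379 and 0.385 against 0.351 and 0.183. A stretch of 18 cytosines in MT-ND5 (positions 12378 to 12417) was at a median of 0.857 and 0.615 in BxPC-3 controls 1 and 2 and at 0 in control 3. In PANC1 it was at 0.824, 0.721 and 0.757 in controls, at 0 at 18 of 18 sites in knockdown 1 and at a median of 1 in knockdown 2, which lay above all PANC1 controls at 15 of 18 sites. In the longest stretch, 23 sites between 13735 and 13786, MiaPaCa-2 knockdowns had medians of 0.258 and 0.25 beside controls of 0.417, 0.25 and 0.4, while the knockdown medians of BxPC-3 and PANC1 were 0.

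Incomplete bisulfite conversion of stretches of mitochondrial RNA may account for these sites: 0.792 of them had another listed site within 10 nt, against 0.0319 of nuclear sites. Few reads kept behind the levels may add to it, since 70.7% of mitochondrial levels at coverage of 100 to 200 (columns exchanged) were fractions with a denominator of 20 or less, against 17.4% of nuclear ones. Low coverage of the stretch is argued against, because the stretch from 12378 to 12417 had a median coverage of at least 121.5 in the libraries with median levels of 0.5 or more, although coverage is then not the number of reads behind a level. Whether the sites depend on NSUN2 cannot be told apart from their selection for a fall: 1 of the 6 knockdown libraries, MiaPaCa-2 knockdown 1, lay above a control of its line in mean mitochondrial level (0.351 against 0.344), by less than the spread of controls. By the rule written for this test such a library counts against dependence, but 1 library with so small a margin cannot decide. The knockdown libraries of PANC1 also disagreed in the stretch from 12378 to 12417. There knockdown 1 was at 0 at 18 of 18 sites, and knockdown 2 lay above all PANC1 controls at 15. NSUN2 dependence therefore stays open. Leaving mitochondrial sites out left 628 of 633 sites falling over all lines.

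The coverage columns of MiaPaCa-2 control 1 and knockdown 2 may have been exchanged in the table. Of the control 1 levels, 0.901 were fractions of 85 to 100% of the coverage in the knockdown 2 column and 0.481 of that in its own; for knockdown 2 the shares were 0.802 and 0.22, and in the other 13 libraries 0.682 to 0.939 with their own column. At sites with under 10 reads in the other column 98.8% of control 1 levels were 0, against 13.3% elsewhere, while controls 2 and 3 averaged 0.208 at the sites with under 10 reads, and the profile of coverage across sites also placed the columns in each other's arm (difference of differences of Spearman correlations 0.0156, 95% interval 0.0105 to 0.0212 over resampled sites). An exchange of the whole libraries is argued against by the level of control 1, which at 0.251 lay with the other MiaPaCa-2 controls, and the denominators at sites with few reads went against an exchange of columns, as 0 of the 2 levels above 0 had one under 10, but 2 levels are too few to decide. A written 0 may then stand for no call at these sites, and no biological explanation was tested.

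Knockdown 1 had higher levels than knockdown 2 in each line, by 0.0276 on average over 638 sites (difference of replicate 2 minus replicate 1, −0.0276; exact two-sided test over 3 lines, p = 0.25, the smallest possible). Lower depth is argued against, because at sites with at least 30 reads in both knockdown libraries of the line (columns exchanged) the mean of knockdown 1 was still 2.11 to 7.94 times that of knockdown 2, a ratio whose size rests on the 0.05 minimum; the minimum is argued against in MiaPaCa-2 and PANC1, where 17 and 43 of these sites were at 0.2 or more in knockdown 1 alone and 5 and 3 in knockdown 2 alone, but not in BxPC-3 (2 and 3). A conversion background alike at all sites is argued against in PANC1, where knockdown 1 exceeded knockdown 2 by 0.185 (95% interval 0.163 to 0.207 over resampled sites) at sites with control levels of at least 0.5, above the 0.1 it could add, while it cannot be told apart in BxPC-3 (0.0951) and MiaPaCa-2 (0.103), nor by the Spearman correlation of knockdown 1 with control levels (0.388 or more), to which the listing of sites that fell adds. More NSUN2 transcript left in knockdown 1 also stays open as a candidate explanation: scaled reads at the NSUN2 site were 1.21, 1.37 and 1.11 times those of knockdown 2 in BxPC-3, MiaPaCa-2 and PANC1, and 1.22 times over the lines (95% interval 1.03 to 1.45, counting error only), with the coverage columns of MiaPaCa-2 exchanged. Within lines the interval included 1 in BxPC-3 (0.831 to 1.76) and PANC1 (0.845 to 1.45) but not in MiaPaCa-2 (1.03 to 1.82). PANC1 had the largest ratio of mean levels (7.94) but the smallest ratio of these reads. As deposited the MiaPaCa-2 order would be the opposite, 251 against 609 scaled reads, and whether the libraries of a number share a hairpin or a batch was not tested.

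Coverage of most genes with listed sites was not shown to change. With exchanged columns, NSUN2 had the smallest p-value of 559 genes (log2 −2.13, limma adjusted p = 1.89e-05), and LRP1, an endocytic receptor, came next with a log2 difference of 1.26 (adjusted p = 0.00368). HFM1 was lower at log2 −3.07 (adjusted p = 0.0247), mostly from BxPC-3, where controls had 4660 ± 2372 scaled reads and knockdowns 32.8 ± 18. These genes were named after their values were seen. In all 2 genes fell and 17 rose (104 with an unadjusted p below 0.05), while the median gene shifted by log2 0.126; with median-ratio scaling only NSUN2 fell and only LRP1 rose, so 16 of the 17 rises were lost, without MiaPaCa-2 NSUN2 was the only gene past the test, and with coverage as deposited MAZ, a zinc finger factor, was (log2 −1.02, adjusted p = 0.00908). The count was 34 without the transcriptomic libraries and 2 to 27 with a library left out, and it was 2 (NSUN2 and LRP1) without BxPC-3 control 2 or knockdown 2, 6 without BxPC-3 knockdown 1 or MiaPaCa-2 knockdown 1, 9 without MiaPaCa-2 control 3 and 4 (NSUN2, LRP1, CD276 and TTC3) without PANC1 knockdown 2. The hypothesis that genes whose sites lost more methylation rose more or fell more in coverage was not borne out. Across 558 genes, which are not independent replicates, the level difference (knockdown minus control) was correlated with the log2 coverage change. The Spearman correlation was −0.0736 (permutation p = 0.0819, two-sided, columns exchanged). Its negative sign means that larger losses went with slightly higher coverage. The size of the coverage change regardless of direction was not tested.

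Other splits of the samples bear on 3 counts. Of 100 splits of control and knockdown labels within lines, 1, the real one, gave as many sites as the 631 over all lines, and the highest other gave 510; since sites were listed for this very split, the count says nothing about chance. Of 100 splits of the control libraries into 3 sets of 3, 3 gave at least 39 sites, the real one included. Few splits did as well, but the highest other gave 161. That split and the other one with 64 sites both kept the BxPC-3 controls together and mixed MiaPaCa-2 with PANC1. The count therefore does not single out the 3 lines as the grouping behind these sites. The split with 161 sites also follows the order of the library means, and whether a shift in level of whole libraries lies behind the 39 sites was not tested. For gene coverage with exchanged columns, 1 of 100 splits, the real one, gave as many as 19 genes, and the highest other gave 1. The exchange was itself argued in part from how coverage followed the arms, so this split is not independent support for the 19 genes.

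Within the spans of protein-coding genes of at least 2000 nt, 472 of 2323 sites lay within 1000 nt of the 3′ end and 314 within 1000 nt of the 5′ end. Over all 2349 sites in spans of protein-coding genes the median relative position was 0.767. Distances are genomic and include introns, and the RNA was enriched for poly(A). No background of covered cytosines was compared, so a preference of m5C for either end was not shown. The highest coverage of any site lay between 6426 and 7843 in all 15 libraries.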
